A study of Mus musculus with 10 samples.

How the data were processed

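RNA bound to EGFP-tagged ribosomes was measured in the cerebral cortex of S100a10-EGFP/Rpl10a mice, a line in which S100a10 regulatory sequences drive the tagged ribosomal protein. In translating ribosome affinity purification (TRAP), tissue is homogenised, tagged polysomes are captured with anti-EGFP antibodies on magnetic beads, and the RNA held by the beads is sequenced. Per the labels, 9 libraries were immunopurified (IP), with 3 from mice that self-administered saline, 3 from mice that self-administered cocaine and 3 from yoked controls, and 1 further library was the saline input. The labels do not say what the yoked mice received, how many animals went into a library, or whether libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The library names place all 3 libraries of a group on one sequencing lane and each group on a lane of its own, with 4 lanes in all, so lane and group cannot be told apart.

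The deposited values are raw read counts per gene symbol, 1 table for each library. The submitters' processing notes name STAR 2.0.0e (an aligner), HTSeq (a read counter) and the mouse genome build mm10. The HTSeq version, its strand setting and the gene annotation are not given in the sources used here. Each table held 32531 genes and 6 entries that name no gene (no feature, ambiguous, low quality, not aligned, not unique and unknown). Those 6 entries were left out of library sizes and tests. Reads aligned to more than 1 place took 38.3% to 46.8% of the reads assigned to genes, ambiguous, without a feature or not unique in the IP libraries and 38.6% in the input. They were not assigned to genes, so counts of genes with near-identical copies are uncertain. That covers many ribosomal protein genes with pseudogenes and the histocompatibility genes whose symbols begin with H2. The mm10 build holds no transgene, so reads of the tagged Rpl10a copy cannot be told from those of the endogenous gene. Without a stated strand setting, reads of overlapping or antisense genes cannot be separated either.

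Counts assigned to genes ranged from 38653752 to 50898401 per IP library, and the input held 69974908. Pairs of libraries within a group differed far beyond counting noise, with a chi-square per degree of freedom between 32.8 and 114 over genes with at least 10 counts in the pair together, so no library was treated as a resequencing of another. Separate preparations from the same animals could also exceed counting noise, so the check does not show that libraries came from separate animals.

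The comparisons, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr (minimum count 10) and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 3 contrasts between IP groups and the joint test of any group difference came from 1 fit of the 9 IP libraries, with 16642 genes tested. Saline IP was compared with input in a fit of all 10 libraries, with 18437 genes tested. The single input has no spread of its own and was assumed to vary like the IP libraries. Levels are CPM, the deposited counts scaled by library size and TMM factors, as mean ± SD over the 3 libraries of a group, and log2 fold changes (log2FC) are given ± SE.

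A set of 38 gene lists was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison. The lists covered activity-dependent genes (immediate early and late secreted), cortical layers (layer 5 intratelencephalic, layer 5 pyramidal tract, layers 2 to 4, layer 6), cell types (excitatory neurons, interneurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, mural cells, meningeal fibroblasts, choroid plexus and ependyma, blood) and neighbouring regions (striatum, hippocampus and thalamus). They also covered dopamine and serotonin signalling, glutamate and GABA receptors, postsynaptic and presynaptic proteins, voltage-gated channels, neuropeptides, chromatin regulators, glucocorticoid, heat shock and interferon responses, the clock, nuclear noncoding RNAs, sex-linked genes, the bait, ribosomal proteins and nuclear-encoded oxidative phosphorylation. One list, the mitochondrially encoded genes, had 0 measured members, which left 37. Each list was also tested with an estimated correlation and with fry, which asks whether members move 1 way on balance and does not compare them with other genes. Counts of members past the threshold are given over all genes and adjusted over the list alone.

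Genes were named by a fixed rule. For each contrast between IP groups, the rule took up to 12 genes each way with the largest fold change among those called, with an average log2 CPM of at least 1 and groups that do not overlap. Directions with fewer than 6 such genes were filled to 6 with the smallest unadjusted p under the same other filters, given as values that did not pass. For IP against input, it took up to 12 each way among those called with an average log2 CPM of at least 3 and the same direction in all 3 saline IP libraries. Symbols of predicted genes, Rik clones and pseudogenes were left out. The rule added from each described list the 2 to 4 members with the smallest p, or the cell type markers with the highest counts, and a fixed set of 14 genes, of which 13 are given (S100a10, Rpl10a, Fos, Fosb, Junb, Egr1, Arc, Bdnf, Malat1, Slc17a7, Gad1, Gfap, Cx3cr1). A few genes that the rule names are not reported here. Of the 8 lower IP-to-input identifiers that are clone names without a match in the annotation, 2 are printed. Ptgds, Rn45s and the genes listed for the libraries numbered 3 were singled out after their values were seen. Coordinates come from the GENCODE M21 annotation of the same build, matched by symbol.

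The test was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed in each of 5 runs. For the cocaine against saline design (16437 genes) it recovered 4.50% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 79.0% of those changed 4-fold, with 5.2 false calls per run. For the saline IP against input design (17830 genes) it recovered 0.750% at 1.5-fold, 10.0% at 2-fold and 61.0% at 4-fold, with 2.6 false calls per run. A planted list of 30 genes changed 1.5-fold in the cocaine against saline design was called by camera in 5 of 5 runs, and 2 of 185 tests of other lists were called. Simulated genes were drawn independently of each other. In the real data the estimated correlation within lists for that contrast ran from -0.01 (heat shock) to 0.78 (meningeal fibroblasts). The simulated 2 of 185 is therefore no measure of false list calls in the real data.

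The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other low-count filters, a 0.1 threshold, a fit with the replicate number as a block, only the groups compared, removal of the 10 most abundant genes, a 2-fold minimum and leaving out each library in turn. Leaving out all libraries numbered 3, and leaving out Rn45s and Lars2 from the comparison with input, were added after the data were seen. The correlation between the cocaine and yoked contrasts, which share the saline libraries, was set against 20 simulations of unchanged groups. Transcript GC content and length were taken from the same annotation for 90.7% of the tested genes.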

Results

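The series profiled ribosome-bound RNA from cortical cells marked by the S100a10-EGFP/Rpl10a transgene in a short-access study of intravenous cocaine self-administration. S100a10 (also known as p11) encodes a calcium-binding family protein that partners annexin A2, and the transgene places a tagged ribosomal protein in cells that use the S100a10 regulatory sequences. There were 3 IP libraries each from the saline, cocaine and yoked groups, and 1 saline input library. Counts assigned to genes were 47905856, 44997249 and 42581837 in the saline IP libraries, 45270915, 44815369 and 48380580 in cocaine, 38653752, 50898401 and 43992581 in yoked, and 69974908 in the input. Between 18944 and 19936 genes had a count in an IP library, against 20416 in the input. Rn45s, the ribosomal RNA precursor, took 4.43% to 9.75% of gene counts in the IP libraries and 7.41% in the input. Ptgds, which encodes the prostaglandin D synthase abundant in the meninges, took 1.94% to 3.80% in the IP libraries and 0.0746% in the input. The share of reads aligned to more than 1 place was 44.9% ± 1.81 in saline (SD, n = 3), 39.9% ± 1.44 in cocaine and 40.5% ± 1.47 in yoked. In two-sided exact permutation tests it differed with p = 0.1 for saline against cocaine and for saline against yoked, the smallest p that 3 against 3 libraries allow, and with p = 0.6 for cocaine against yoked.

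The comparison of saline IP with input asked which transcripts the purification selects. The transcript of S100a10, whose regulatory sequences drive the tagged protein, was enriched in IP. S100a10 (chromosome 3, 93555080 to 93564643, plus strand, GRCm38) was at 235 ± 56.1 CPM in saline IP (SD, n = 3) and 35.3 CPM in the input, a log2FC of 2.73 ± 0.31 or 6.66-fold (edgeR quasi-likelihood test, adjusted p = 7.52e-05). Transcripts of the meninges were enriched still more, so the S100a10 rise does not by itself show which cells it came from. Among transcripts typical of meningeal fibroblasts, that of the proteoglycan decorin (Dcn) was 10.9-fold higher in IP, that of the collagen Col1a2 32.8-fold and that of the transporter Slc13a4 33.6-fold. Most interferon-response transcripts were also higher, as were 6 of 20 endothelial and 6 of 12 mural markers, and these list calls were lost with an estimated correlation (adjusted p = 0.150, 0.386 and 0.270). Nuclear noncoding RNAs were lower in IP. Lists of oligodendrocyte, interneuron and striatal neuron markers were called lower too, but not with an estimated correlation (adjusted p = 0.390, 0.386 and 0.268). In all, 1304 genes were higher and 785 lower in IP of 18437 tested (2089 called by edgeR, and 2704 of 18291 by DESeq2). Without saline replicate 1, 1047 were higher and 417 lower.

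Among the 14 meningeal fibroblast markers, 13 rose in IP over all genes and 14 adjusted over the list alone, with a median log2FC of 4.54 (camera adjusted p = 4.69e-44). That list had an adjusted p = 0.0751 with an estimated correlation. Serping1, the complement C1 inhibitor, rose by 5.14 ± 0.32, Mgp, the matrix Gla protein, by 4.99 ± 0.31, the GABA and taurine transporter Slc6a13 by 4.75 ± 0.40, and Islr by 4.09 ± 0.36. By level, the sulfate transporter Slc13a4 (chromosome 6, 35267957 to 35308131, minus strand) was at 380.05 ± 97.9 CPM in saline IP against 11.3 CPM in input, Col1a2 at 78.4 ± 18.6 against 2.39 CPM, and Dcn at 114 ± 7.09 against 10.4 CPM. The list's median was 3.90 to 4.88 above the input in each of the 9 IP libraries. Ptgds was at 30155 ± 7451.8 CPM against 780 CPM in input.

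**Figure D1:**
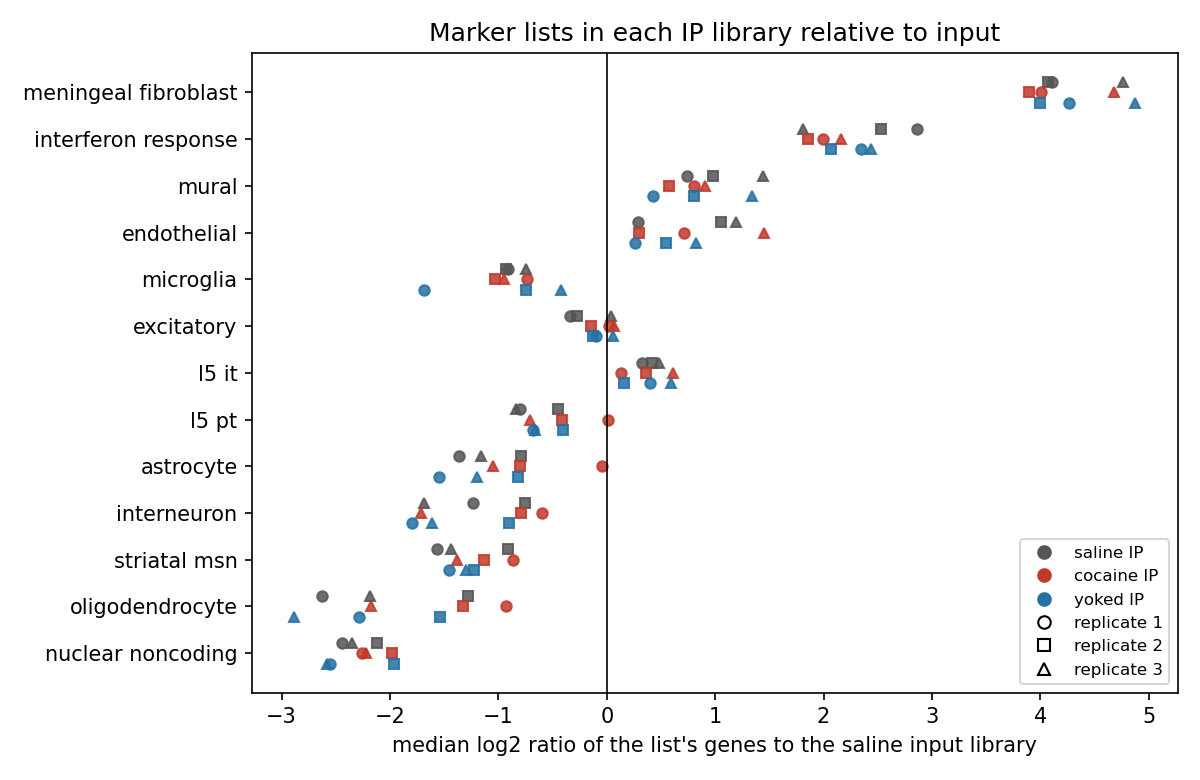
Median log2 ratio to the saline input of 13 gene lists, 1 point for each of the 9 IP libraries, with colour for the group and shape for the replicate number. Meningeal fibroblast markers lie at 3.90 to 4.88 in the 9 libraries and nuclear noncoding RNAs at -2.58 to -1.97, with oligodendrocyte markers spread from -2.88 to -0.93.

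The genes with the largest enrichment included several known outside neurons. Tspan8, which encodes a tetraspanin (chromosome 10, 115816832 to 115849893, plus strand), had a log2FC of 7.39 ± 0.55, a ratio that rests on only 5 counts in the input. The organic cation transporter Slc22a2 rose by 6.97 ± 0.82, H2-Q1 by 6.30 ± 1.0, the methyltransferase Inmt by 5.93 ± 0.77 and the aldehyde oxidase Aox3 by 5.89 ± 0.34. Transcripts for the signalling protein Wnt6 (5.76 ± 0.73) and the homeobox factor Alx4 (5.71 ± 0.42) rose, as did Dapl1 (5.64 ± 0.48), Ppic (5.47 ± 0.41) and the retinoic acid binding protein Crabp2 (5.40 ± 0.33). Adjusted p for these 10 genes ranged from 8.59e-07 to 0.00103. Low input levels also underlie the ratios of Slc22a2 (125-fold at an average log2 CPM of 3.77), Inmt (61.0-fold at 3.86) and Wnt6 (54.3-fold at 3.46).

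Of 20 interferon-response genes, 15 rose over all genes and 16 adjusted over the list alone, with a median log2FC of 2.75 (camera adjusted p = 5.60e-19; adjusted p = 0.150 with an estimated correlation). Ifitm3 rose by 4.33 ± 0.32, Oasl2 by 4.08 ± 0.40 and Ifit1 by 3.62 ± 0.42. In the endothelial list 6 of 20 markers rose and 1 fell, the same counts adjusted over the list alone, with Cdh5 (vascular cadherin) at 4.83 ± 0.60, the efflux pump Abcb1a at 4.75 ± 0.51 and Itm2a at 3.76 ± 0.28 (list adjusted p = 0.000156; adjusted p = 0.386 with an estimated correlation). In the mural list 6 of 12 markers rose, with 6 higher and 1 lower adjusted over the list alone, among them Vtn at 3.77 ± 0.45 and Myl9 at 3.56 ± 0.37 (list adjusted p = 0.00122; adjusted p = 0.270 with an estimated correlation). Glucocorticoid-responsive genes (median 0.34; adjusted p = 0.0251, and adjusted p = 0.386 with an estimated correlation) had 4 of 21 members higher and, adjusted over the list alone, 6 higher and 1 lower, led by Sult1a1 at 4.18 ± 0.36 and Txnip at 3.09 ± 0.32. Oxidative phosphorylation genes had a median of 0.52 with 74 of 82 members above 0 (adjusted p = 0.000248; adjusted p = 0.585 with an estimated correlation), but 2 members rose, Ndufa13 at 0.82 ± 0.22 and Atp5d at 0.70 ± 0.20, and 0 adjusted over the list alone. By library, the median log2 ratio of that list to input was 0.59 and 0.69 in saline replicates 1 and 2, but 0.10 in saline replicate 3. The bait list of S100a10 and Rpl10a was called (adjusted p = 0.0264; adjusted p = 0.366 with an estimated correlation) through S100a10, while Rpl10a was at -0.04 ± 0.32.

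Nuclear noncoding RNAs were the list most depleted by median, and the call held with an estimated correlation (median -2.25; adjusted p = 3.61e-16; adjusted p = 0.0487 with an estimated correlation). Over all genes and adjusted over the list alone, 7 of 12 fell. Malat1 (chromosome 19, 5795690 to 5802672, minus strand, lincRNA) fell by 4.98 ± 0.39, from 3732.7 CPM in input to 119 ± 21.9 CPM, Meg3 fell by 3.69 ± 0.34, Snhg11 fell by 3.27 ± 0.24 and Snhg14 fell by 2.67 ± 0.22. Cdr1, best known as the locus of a circular RNA, fell by 3.85 ± 0.35. The identifiers AK140265 (-8.98 ± 0.55; 86.6 ± 38.4 CPM in saline IP and 43797 in input) and GU332589 (0.630 ± 0.0501 CPM in saline IP and 324 in input) fell most among the genes named by rule and have no match in the annotation used.

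Oligodendrocyte markers had a median of -2.02, with 6 of 20 lower and 1 higher over all genes and 16 lower and 1 higher adjusted over the list alone (adjusted p = 2.14e-05; adjusted p = 0.390 with an estimated correlation). The myelin genes Mobp (-2.25 ± 0.44) and Mbp (-1.92 ± 0.40) fell, while Gsn, which encodes gelsolin, rose (1.70 ± 0.31). Interneuron markers had a median of -1.21, with 5 of 24 lower and 10 adjusted over the list alone, including Erbb4 (-2.02 ± 0.44), Sox6 (-2.10 ± 0.49), Reln (-1.42 ± 0.39) and Pvalb (-2.37 ± 0.68) (adjusted p = 0.000119; adjusted p = 0.386 with an estimated correlation). Striatal neuron markers had a median of -1.25, with 8 of 17 lower and 10 adjusted over the list alone, including Adora2a (-2.37 ± 0.40), Drd1 (-1.85 ± 0.32) and Pde10a (-1.33 ± 0.22) (adjusted p = 2.88e-05; adjusted p = 0.268 with an estimated correlation). In the overlapping dopamine list 8 of 24 fell, also 8 adjusted over the list alone (median -0.24; adjusted p = 0.0121, and adjusted p = 0.366 with an estimated correlation). Microglial markers had a median of -0.93 (adjusted p = 0.0233; adjusted p = 0.502 with an estimated correlation), with 3 of 20 lower and 1 higher, and 4 and 1 adjusted over the list alone. Among them the receptor P2ry12 fell (-1.96 ± 0.41), and Tmem119 rose (1.77 ± 0.38). Blood markers had 1 of 6 lower, Hbb-bs at -2.25 ± 0.46, and 3 adjusted over the list alone (median -1.76; adjusted p = 0.0217, and adjusted p = 0.268 with an estimated correlation).

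Within neurons, the general excitatory list was near the input (median -0.17, adjusted p = 0.309, 1 of 16 lower over all genes and adjusted over the list alone), and the glutamate transporter Slc17a7 was at 0.00 ± 0.51. Markers of layer 5 intratelencephalic neurons had a median of 0.34 and did not pass as a list (adjusted p = 0.0873), but 3 of 14 rose, the same number adjusted over the list alone: S100a10 itself, Endou (1.91 ± 0.51) and Whrn (1.49 ± 0.43). Layer 5 pyramidal tract markers were lower (median -0.79; adjusted p = 0.0243, and adjusted p = 0.432 with an estimated correlation), with 3 of 14 down and 1 up, and 6 and 1 adjusted over the list alone, led by Bcl11b at -1.76 ± 0.36. Markers of layers 2 to 4 were also lower (median -0.64; adjusted p = 0.0121, and adjusted p = 0.386 with an estimated correlation), with 4 of 14 down and 1 up, and 6 and 2 adjusted over the list alone. Of these, Inhba fell by 1.67 ± 0.30 and Otof fell by 1.77 ± 0.41, and Plcxd2 rose by 1.17 ± 0.23. Receptor and channel lists were lower too. Glutamate receptors (median -0.57) had 7 of 29 lower, with 11 lower and 1 higher adjusted over the list alone, including Grik3 at -1.50 ± 0.34 and Grin3a at -1.39 ± 0.32. GABA receptors (median -0.65) had 2 of 16 lower and 4 adjusted over the list alone, led by Gabra3 at -1.17 ± 0.20. Voltage-gated channels (median -0.36) had 8 of 52 lower and 11 adjusted over the list alone, led by the potassium channels Kcnn2 at -2.46 ± 0.30 and Kcna1 at -1.06 ± 0.20. Camera gave adjusted p = 0.000248, 0.00312 and 0.000248 for the 3 lists in that order, and adjusted p = 0.489, 0.386 and 0.540 with an estimated correlation. Late activity-dependent secreted genes (median -0.81; adjusted p = 0.00122, and adjusted p = 0.187 with an estimated correlation) had 4 of 16 lower and 8 adjusted over the list alone, including Penk at -1.50 ± 0.35 and Bdnf at -1.14 ± 0.33. Bdnf missed the threshold without saline replicate 1 (-0.93, adjusted p = 0.0964) and without saline replicate 2 (-1.17, adjusted p = 0.0593).

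For 2 lists with weaker shifts, the call was lost when single libraries were left out. Neuropeptides (median -0.53) had 4 of 20 lower, and 7 lower and 1 higher adjusted over the list alone, among them Grp at -1.85 ± 0.43. That list passed with adjusted p = 0.0288 (adjusted p = 0.268 with an estimated correlation). It missed without saline replicate 1, where the median was larger (-0.80, adjusted p = 0.0552), or saline replicate 3 (-0.42, adjusted p = 0.0542). Presynaptic vesicle genes (median -0.23) had 3 of 32 lower and 1 higher by both adjustments, that is over all genes and adjusted over the list alone. They passed with adjusted p = 0.0243 (adjusted p = 0.502 with an estimated correlation) and missed without saline replicate 1 (-0.16, adjusted p = 0.0963). Sv2c fell by 1.44 ± 0.40 and Stx1a rose by 0.86 ± 0.21.

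The other 15 lists were not called against input. Some members of those lists moved in opposite directions. Of 20 astrocyte markers (median -1.18, adjusted p = 0.122), Gjb6 (3.57 ± 0.38) and Apoe (1.65 ± 0.21) were among 4 that rose, and Aqp4 (-3.04 ± 0.57) and Fgfr3 (-2.10 ± 0.36) among 6 that fell, with 5 and 10 adjusted over the list alone. Of 41 immediate early genes (median 0.10, adjusted p = 0.701), 4 rose and 3 fell, with 6 and 4 adjusted over the list alone. Klf4 rose by 4.90 ± 0.50, whereas Fos (0.96 ± 0.30, adjusted p = 0.0552), Egr1 (0.30 ± 0.25), Arc (0.31 ± 0.33), Junb (0.01 ± 0.36) and Fosb (-0.65 ± 0.29) did not pass. Without saline replicate 1, Fos passed (1.10, adjusted p = 0.0369). In the serotonin list, Anxa2 (4.25 ± 0.27) and Ahnak (2.71 ± 0.49), whose proteins bind p11, rose over all genes and adjusted over the list alone. The median of that list was -0.37, its mean 0.09 and its test pointed up (adjusted p = 0.543). Oligodendrocyte precursor markers (median -1.53, adjusted p = 0.237) had 3 of 10 lower and 1 higher, with 4 and 2 adjusted over the list alone, and Bmp4 rose by 4.39 ± 0.44. Layer 6 (median -0.84, adjusted p = 0.237) had 2 higher, among them Osr1 at 4.79 ± 0.33, and 3 lower, with 2 and 7 adjusted over the list alone. Choroid plexus and ependyma (median 0.11, adjusted p = 0.221) had 3 of 10 higher and 4 adjusted over the list alone, led by Kl at 2.82 ± 0.45. The hippocampus and thalamus list (-0.62, adjusted p = 0.203) had 2 higher and 2 lower by both, over all genes and adjusted over the list alone. Postsynaptic scaffold genes (-0.32, adjusted p = 0.122) and chromatin regulators (-0.14, adjusted p = 0.217) each had 1 higher and 1 lower, unchanged when adjusted over the list alone, with Kalrn at 2.47 ± 0.24 and Hdac1 at 1.33 ± 0.32 as the ones that rose. In the heat shock list (0.01, adjusted p = 0.375) Hspb1 rose by 4.30 ± 0.45, and among sex-linked genes (-0.31, adjusted p = 0.158) Uty fell by 1.19 ± 0.22, each also when adjusted over the list alone. Ribosomal proteins (0.32, adjusted p = 0.0635) had 1 of 86 higher, Rps27l at 1.90 ± 0.52, and 0 adjusted over the list alone, and clock genes (0.30, adjusted p = 0.187) had 0 by both, over all genes and adjusted over the list alone. Of the remaining fixed genes, Cx3cr1 fell (-1.77 ± 0.51, adjusted p = 0.0398), though not without saline replicate 1 (-1.56, adjusted p = 0.110) or saline replicate 2 (-1.85, adjusted p = 0.0593). Gfap (-2.39 ± 0.76, adjusted p = 0.0613) passed only without saline replicate 2 among the libraries left out (-3.24, adjusted p = 0.0132), and Gad1 was at -1.37 ± 0.52 (adjusted p = 0.110).

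Cocaine against saline self-administration is the comparison the study's title names. Transcripts of the translation and respiration machinery stood lower in cocaine: 80 of 86 ribosomal protein genes and 73 of 82 oxidative phosphorylation genes had lower values. Once each library's trend on transcript length was removed, most of the shift was gone: the median of the cocaine and yoked libraries together against saline went from -0.28 to -0.09 for ribosomal proteins and from -0.25 to -0.04 for oxidative phosphorylation. Interferon-response genes were lower in 18 of 20 cases. Oligodendrocyte and astrocyte markers stood higher, with 18 of 20 and 17 of 20 above saline, and so did immediate early genes such as Egr1 and Egr2. Microglial markers (median 0.03, camera adjusted p = 0.472) and oligodendrocyte precursor markers (0.53, adjusted p = 0.0764) were not called. No list call held with an estimated correlation (lowest adjusted p = 0.550) or with fry (0.736). No single gene passed. Of 16642 genes, edgeR called 0 (530 at an unadjusted p under 0.05, against 832.1 by chance) and limma-voom called 0 (552 unadjusted). DESeq2, with 22809 genes tested, called 0 (717 unadjusted). The edgeR count of 530 moved with the fit, so its place below 832.1 did not hold throughout. It was 1154 with the replicate block, 1547 without the libraries numbered 3 and 1117 without saline replicate 3, but 233 without cocaine replicate 1.

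The ribosomal protein list had a median log2FC of -0.32 (camera adjusted p = 9.53e-14) and the oxidative phosphorylation list -0.28 (adjusted p = 1.01e-12), each with an adjusted p = 0.550 with an estimated correlation. Members with the smallest p were Rplp1 (-0.59 ± 0.16), Rpl37 (-0.61 ± 0.20) and Rplp2 (-0.48 ± 0.17), and Ndufa13 (-0.40 ± 0.15), Uqcr11 (-0.53 ± 0.20) and Uqcrq (-0.45 ± 0.17). Relative to the mean of the 9 IP libraries, the ribosomal protein median was 0.36, 0.39 and -0.20 in saline, -0.13, 0.13 and -0.33 in cocaine and 0.11, -0.14 and -0.16 in yoked, so saline replicate 3 lay with the other groups. The share of reads aligned to more than 1 place, given above, was also higher in saline. Interferon-response genes had a median of -0.37 (adjusted p = 7.99e-05; adjusted p = 0.550 with an estimated correlation), with Psmb8 at -0.72 ± 0.20, Ifit2 at -0.50 ± 0.20 and H2-D1 at -0.48 ± 0.22. Without saline replicate 1 that list was at -0.13 (adjusted p = 0.327). Meningeal markers had a median of -0.24 (adjusted p = 0.00640; adjusted p = 0.704 with an estimated correlation), with Mgp at -0.30 ± 0.15, and were not called without saline replicate 3 (-0.10, adjusted p = 0.610), cocaine replicate 1 (-0.18, adjusted p = 0.0863) or cocaine replicate 2 (-0.13, adjusted p = 0.357).

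Oligodendrocyte markers had a median of 0.51 (adjusted p = 0.000289) and astrocyte markers 0.40 (adjusted p = 0.000521), each with an adjusted p = 0.550 with an estimated correlation. Examples are Ugt8a (1.01 ± 0.55), an enzyme of myelin lipid synthesis, Fa2h (0.95 ± 0.52), the GABA transporter Slc6a11 (0.83 ± 0.39) and the water channel Aqp4 (0.85 ± 0.47). The oligodendrocyte median relative to the IP mean was 0.98, 0.60 and -0.34 in cocaine and -0.61, 0.64 and -0.39 in saline, so the groups overlapped. The oligodendrocyte call was lost without cocaine replicate 1 (0.22, adjusted p = 0.110), saline replicate 1 (0.27, adjusted p = 0.107) or saline replicate 3 (0.38, adjusted p = 0.0546), and the astrocyte call without cocaine replicate 1 (0.07, adjusted p = 0.160).

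Immediate early genes had a median of 0.17 with 26 of 41 above 0 (adjusted p = 0.00213; adjusted p = 0.550 with an estimated correlation). Egr1 was at 1094.2 ± 106 CPM in cocaine and 777 ± 125 CPM in saline (SD, n = 3 each). Its log2FC was 0.48 ± 0.17, that of Egr2 0.76 ± 0.28, Fosl2 0.44 ± 0.16 and Egr3 0.52 ± 0.21. Without saline replicate 1 the list was at 0.13 (adjusted p = 0.125). Fos was at 0.25 ± 0.20, Fosb at 0.33 ± 0.21, Arc at 0.33 ± 0.23, Bdnf at 0.38 ± 0.24 and Junb at 0.05 ± 0.25. Layer 5 pyramidal tract markers (median 0.28, adjusted p = 0.00213), markers of layers 2 to 4 (0.12, adjusted p = 0.00724), chromatin regulators (0.12, adjusted p = 0.00213), presynaptic genes (0.09, adjusted p = 0.00478) and clock genes (0.13, adjusted p = 0.0298) were called higher, each with an adjusted p = 0.550 with an estimated correlation. Postsynaptic scaffold genes (0.14, adjusted p = 0.00266) had an adjusted p = 0.644 with an estimated correlation. Examples are Bcl6 (0.54 ± 0.21), Fezf2 (0.27 ± 0.14), Rasgrf2 (0.44 ± 0.21), Smarca2 (0.28 ± 0.13), Syn1 (0.27 ± 0.13), Per2 (0.34 ± 0.18) and Camk2a (0.37 ± 0.16). Without saline replicate 1 the calls of layers 2 to 4 (0.14, adjusted p = 0.252), presynaptic (-0.01, adjusted p = 0.480) and postsynaptic genes (0.08, adjusted p = 0.218) were lost. The postsynaptic call was also lost without saline replicate 2 (0.05, adjusted p = 0.127) or cocaine replicate 3 (0.03, adjusted p = 0.247). The clock call was lost without cocaine replicate 1 (0.11, adjusted p = 0.0596), cocaine replicate 2 (0.15, adjusted p = 0.172), saline replicate 2 (0.10, adjusted p = 0.231) or saline replicate 3 (0.14, adjusted p = 0.0508). In all 13 called lists, 0 members passed over all genes and 0 adjusted over the list alone.

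Among genes taken for their small unadjusted p, each with an edgeR adjusted p of 0.990, the higher ones were Ptprz1 (0.91 ± 0.30), a receptor phosphatase of glia, Acot11 (0.73 ± 0.25), Frmd5 (0.61 ± 0.19), the adaptor Shc4 (0.59 ± 0.19), AB346318 (0.54 ± 0.15) and Arid5b (0.48 ± 0.16). The lower ones beside Rplp1 (chromosome 9, 61913284 to 61914542, minus strand) and Psmb8 were Aldh16a1 (-0.86 ± 0.24), Fbxl4 (-0.65 ± 0.18), Lars2 (-0.59 ± 0.17) and the imprinted gene Nnat (-0.56 ± 0.17). Rplp1 was at 113 ± 8.76 CPM in cocaine, 108 ± 3.68 in yoked and 169 ± 34.3 in saline (SD, n = 3 each). S100a10 was at -0.32 ± 0.18 and Rpl10a at -0.25 ± 0.23, and Slc17a7 (-0.18 ± 0.36), Gad1 (0.46 ± 0.40), Gfap (0.62 ± 0.62), Cx3cr1 (0.83 ± 0.41) and Malat1 (0.17 ± 0.30) also did not pass. The groups did not overlap for 8.97% of genes, against 10% by chance, a level that takes no account of the replicate numbers. The median SE of a log2FC was 0.226, and in the simulation changes of 1.5-fold were mostly missed.

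The yoked group against saline showed lower ribosomal protein and oxidative phosphorylation transcripts as well, with 81 of 86 and 74 of 82 members below saline. For the cocaine and yoked libraries together against saline, removal of the length trend took these medians from -0.28 to -0.09 and from -0.25 to -0.04. Interneuron markers stood lower in 22 of 24 cases. Clock genes, postsynaptic scaffold genes and immediate early genes stood higher. No list call held with an estimated correlation (lowest adjusted p = 0.528) or with fry (0.780). No single gene passed: edgeR called 0 of 16642 (398 at an unadjusted p under 0.05), limma-voom 0 (384) and DESeq2 0 of 22809 (565). The edgeR count of 398 was 690 with the replicate block, 1005 without the libraries numbered 3 and 929 without saline replicate 3, but 254 with only the 2 groups compared.

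Ribosomal proteins had a median of -0.30 (camera adjusted p = 5.02e-13), oxidative phosphorylation -0.22 (adjusted p = 1.87e-10), interneuron markers -0.25 (adjusted p = 0.00915) and interferon-response genes -0.22 (adjusted p = 0.0266), each with an adjusted p = 0.811 with an estimated correlation. Examples are Rplp1 (-0.65 ± 0.16), Rplp2 (-0.40 ± 0.17), Uqcc2 (-0.53 ± 0.24), the inhibitory transmitter genes Npy (-0.49 ± 0.23) and Slc32a1 (-0.58 ± 0.32), and Psmb8 (-0.69 ± 0.20). The interneuron list rested on saline replicate 2, which had the highest level of these markers in saline (0.47 above the IP mean, against -0.00 and -0.54). Without it the median was 0.06 (adjusted p = 0.935), and the call was also lost without yoked replicate 1 (-0.18, adjusted p = 0.247) or yoked replicate 3 (-0.14, adjusted p = 0.446). The interferon list was at 0.05 without saline replicate 1 (adjusted p = 0.497) and at -0.12 without yoked replicate 2 (adjusted p = 0.388).

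Clock genes had a median of 0.13 with 15 of 20 above 0 (adjusted p = 0.000575; adjusted p = 0.528 with an estimated correlation). Bhlhe40 was at 0.41 ± 0.13, Per1 at 0.51 ± 0.19, Per2 at 0.41 ± 0.18 and Cry1 at 0.34 ± 0.17. Immediate early genes had a median of 0.15 (adjusted p = 0.00865; adjusted p = 0.560 with an estimated correlation). Egr2 was at 0.86 ± 0.28, Egr1 at 0.42 ± 0.17 and Fosl2 at 0.37 ± 0.16, while Ier2 was at -0.75 ± 0.23. That call was lost without saline replicate 1 (0.11, adjusted p = 0.255) or yoked replicate 1 (0.10, adjusted p = 0.0944). Egr2 (chromosome 10, 67535475 to 67542188, plus strand) was at 22.4 ± 3.16 CPM in yoked, 21.1 ± 9.59 in cocaine and 12.4 ± 3.17 in saline (SD, n = 3 each). Postsynaptic scaffold genes (0.12, adjusted p = 0.000575), chromatin regulators (0.10, adjusted p = 0.00552) and voltage-gated channels (0.09, adjusted p = 0.00894) were higher, each with an adjusted p = 0.811 with an estimated correlation, with Dlg2 (0.23 ± 0.13), Tet3 (0.52 ± 0.26) and Cacnb4 (0.19 ± 0.12) as examples. The channel list was at -0.08 without yoked replicate 3 (adjusted p = 0.647), -0.01 without saline replicate 1 (0.875) and -0.04 without saline replicate 2 (0.864). The postsynaptic call was lost without saline replicate 1 (0.07, adjusted p = 0.155), saline replicate 2 (0.08, adjusted p = 0.0533) or yoked replicate 3 (0.03, adjusted p = 0.453). The chromatin call was lost without saline replicate 1 (0.08, adjusted p = 0.0772), saline replicate 2 (0.08, adjusted p = 0.0512), yoked replicate 2 (0.08, adjusted p = 0.146) or yoked replicate 3 (0.09, adjusted p = 0.122). In the 9 called lists, 0 members passed over all genes and 0 adjusted over the list alone.

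By small unadjusted p, with an edgeR adjusted p of at least 0.999 each, Shc4 (0.72 ± 0.19), Ak4 (0.48 ± 0.15) and AB346318 (0.45 ± 0.15) stood higher in yoked beside Egr2 and Bhlhe40. The Wnt-binding protein gene Sfrp4 (-1.07 ± 0.24), Hspb2 (-0.86 ± 0.24), Kazald1 (-0.79 ± 0.21) and Pcbd1 (-0.68 ± 0.19) stood lower beside Rplp1. Fos (0.30 ± 0.20), Fosb (0.43 ± 0.21), Arc (0.25 ± 0.23), Bdnf (0.41 ± 0.24), Junb (-0.15 ± 0.26), S100a10 (-0.22 ± 0.18), Rpl10a (-0.14 ± 0.23), Slc17a7 (0.08 ± 0.36), Gad1 (-0.15 ± 0.40), Gfap (-0.06 ± 0.62), Cx3cr1 (0.14 ± 0.42) and Malat1 (0.46 ± 0.30) did not pass. Groups did not overlap for 6.08% of genes, against 10% by chance, a level that takes no account of the replicate numbers.

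Cocaine against yoked gave its largest called list shifts in markers of oligodendrocytes, interneurons and astrocytes, and 0 lists were called with an estimated correlation (lowest adjusted p = 0.542) or with fry (0.980). Oligodendrocyte markers stood higher in cocaine in 19 of 20 cases, interneuron markers in 23 of 24, astrocyte markers in 16 of 20 and markers of layer 5 pyramidal tract neurons in 12 of 13. Ribosomal protein (median -0.06, adjusted p = 0.392), oxidative phosphorylation (-0.04, adjusted p = 0.202) and immediate early genes (0.03, adjusted p = 0.599) were not called. No single gene passed: edgeR called 0 of 16642 (159 at an unadjusted p under 0.05), limma-voom 0 (153) and DESeq2 0 of 22809 (264). The edgeR count of 159 was 439 with the replicate block, 459 without the libraries numbered 3 and 600 without cocaine replicate 3, but 81 without cocaine replicate 1.

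The oligodendrocyte list had a median of 0.70 (camera adjusted p = 1.36e-11), interneurons 0.48 (adjusted p = 2.72e-08), astrocytes 0.36 (adjusted p = 1.70e-07), layer 5 pyramidal tract markers 0.14 (adjusted p = 0.00528) and neuropeptides 0.17 (adjusted p = 0.0455), each with an adjusted p = 0.542 with an estimated correlation. Examples are the transferrin gene Trf (0.77 ± 0.31), Aspa (0.56 ± 0.24), Slc32a1 (0.65 ± 0.32), Sox6 (0.71 ± 0.39), Pvalb (0.98 ± 0.55), Slc6a11 (0.95 ± 0.39), Vat1l (0.44 ± 0.25) and Penk (0.44 ± 0.27). Per library the oligodendrocyte median relative to the IP mean was 0.98, 0.60 and -0.34 in cocaine and -0.22, 0.33 and -0.95 in yoked, and the interneuron median 0.66, 0.41 and -0.31 against -0.35, 0.28 and -0.42. In both groups the library numbered 3 was the lowest. Meningeal markers were below yoked in 14 of 14 cases (median -0.12; adjusted p = 0.0455, and adjusted p = 0.833 with an estimated correlation), with Col3a1 at -0.29 ± 0.22. That list turned to 0.09 without yoked replicate 3 (adjusted p = 0.413), and was not called without cocaine replicate 1 (-0.05, adjusted p = 0.409), cocaine replicate 2 (0.01, adjusted p = 0.641) or saline replicate 1 (-0.12, adjusted p = 0.0612). The layer 5 call was lost without cocaine replicate 1 (0.08, adjusted p = 0.0988) or yoked replicate 1 (0.05, adjusted p = 0.532). The neuropeptide call was lost without cocaine replicate 2 (median 0.12) or cocaine replicate 3 (0.0053). With the median little changed, it was also lost without yoked replicate 2 (0.17), yoked replicate 3 (0.17) or saline replicate 1 (0.18). Adjusted p in these fits ran from 0.0528 to 0.190. Without all libraries numbered 3 the call was lost as well (0.08, adjusted p = 0.1475). In these 6 lists, 0 members passed over all genes and 0 adjusted over the list alone.

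**Figure D2:**
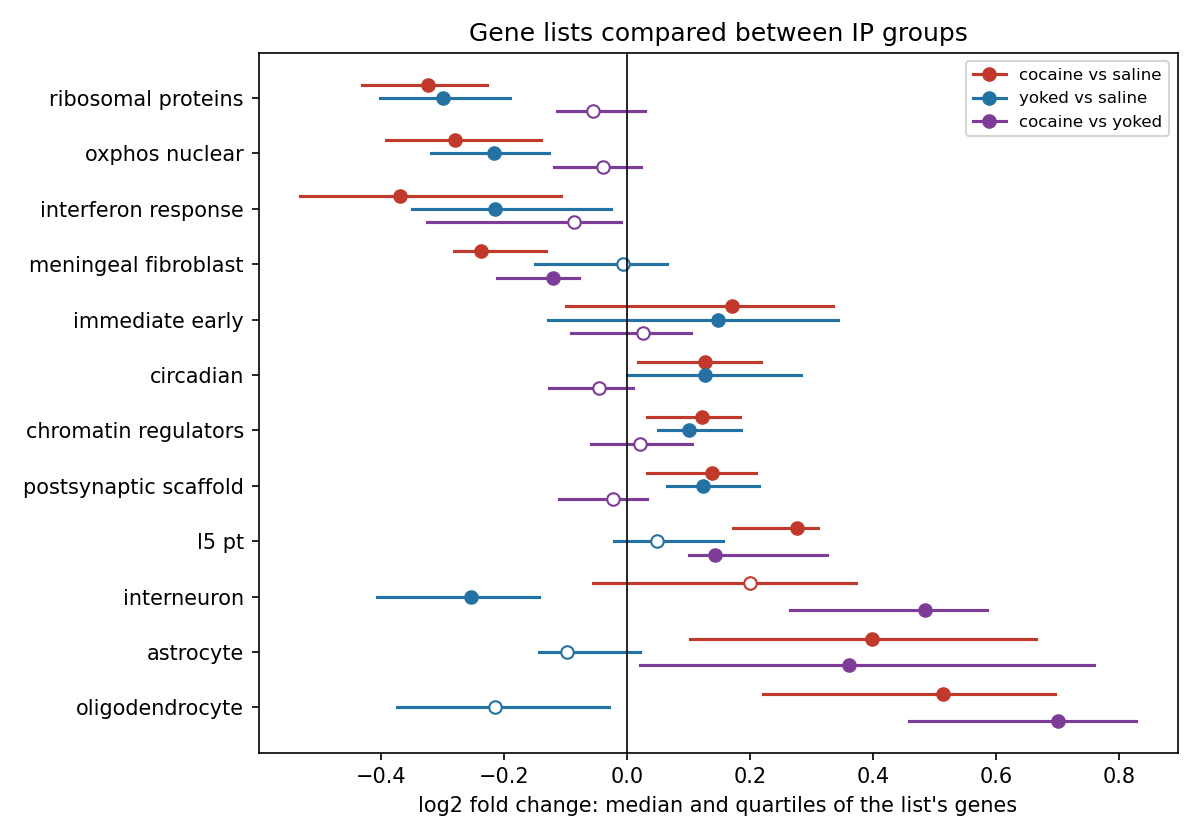
Median log2 fold change of 12 gene lists in the 3 contrasts between IP groups, with bars for the quartiles over members; filled points passed camera at an adjusted p under 0.05 with the preset correlation and open points did not. Ribosomal protein medians lie at -0.32 and -0.30 against saline and at -0.06 between cocaine and yoked, and the oligodendrocyte median is at 0.70 for cocaine against yoked.

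By small unadjusted p, with an edgeR adjusted p of at least 0.999 each, the acute-phase gene Serpina3n was at 2.11 ± 0.58. It had 15.5, 11.4 and 5.66 CPM in cocaine and 1.09, 3.18 and 3.18 CPM in yoked, with saline at 4.41, 3.55 and 16.2 CPM. Rpp25 (0.87 ± 0.27), the growth factor receptor Fgfr3 (0.83 ± 0.30), Lekr1 (0.72 ± 0.24), AI464131 (0.77 ± 0.27) and Dner (0.51 ± 0.18) followed. On the lower side were the interferon-induced Rsad2 (-1.57 ± 0.49), Calml4 (-1.18 ± 0.40), Lrrc23 (-0.92 ± 0.34), Mpeg1 (-0.80 ± 0.31), Fibin (-0.67 ± 0.23) and Pik3r6 (-0.60 ± 0.23). Egr1 (0.06 ± 0.17), Fos (-0.05 ± 0.20), Fosb (-0.10 ± 0.21), Arc (0.09 ± 0.23), Junb (0.20 ± 0.26), Bdnf (-0.03 ± 0.24), S100a10 (-0.10 ± 0.18), Rpl10a (-0.11 ± 0.23), Slc17a7 (-0.26 ± 0.36), Gad1 (0.61 ± 0.40), Gfap (0.68 ± 0.62), Cx3cr1 (0.70 ± 0.41) and Malat1 (-0.29 ± 0.30) did not pass. Groups did not overlap for 4.74% of genes, against 10% by chance, a level that takes no account of the replicate numbers.

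The joint test of any difference among the 3 groups called 0 genes with edgeR (268 at an unadjusted p under 0.05) and 0 with limma-voom (263). With DESeq2, 22809 genes were tested and 0 called (477 unadjusted). The edgeR count of 268 was 684 with the replicate block, 980 without the libraries numbered 3 and 635 without saline replicate 3, but 179 without cocaine replicate 1. Across genes, which are not independent replicates, the cocaine-saline and yoked-saline fold changes correlated with r = 0.589. These contrasts share the saline libraries, and 20 simulations of unchanged groups gave a mean r of 0.503 (0.484 to 0.524). Genes were simulated independently, so that range may be too narrow for genes that move together within libraries. The covariance was 0.0891, against 0.0704 simulated, a difference of 0.0186. The value expected from the spread of the saline libraries was 0.0827. For the 5674 genes with an average log2 CPM of at least 5 the covariance was 0.0184 against 0.0210 simulated, a difference of -0.00266. There the saline spread gave 0.0220. The simulations and the saline spread both count the shift of the libraries numbered 3 as independent noise. In the real contrasts that shift largely cancels, since each group holds such a library, so both values may be too large. A covariance below them therefore does not show that no change is shared. With 3 saline libraries the controls could not be split into sets of at least 2, so part of the excess may come from the shared controls.

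**Figure D3:**
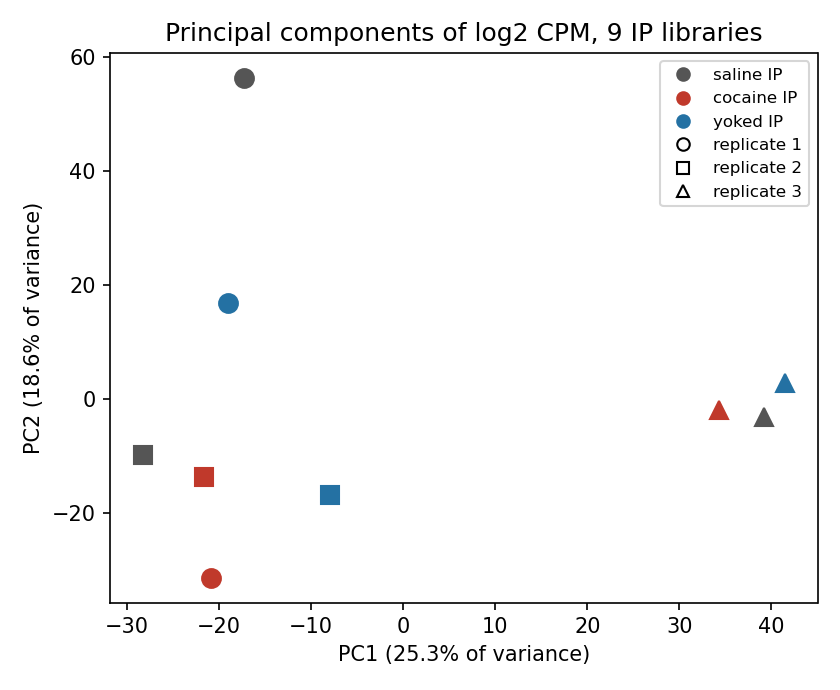
First and second principal components of log2 CPM in the 9 IP libraries, with colour for the group and shape for the replicate number. The 3 libraries numbered 3 lie at 34.3 to 41.5 on the first component (25.3% of the variance) and the other 6 at -28.3 to -7.92, and the groups do not separate.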

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

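Of the tests in this part, the depth, carry-over, lane, choice of 1 library per replicate number, nonspecific binding, meninges and sample-split tests were chosen only after the results they bear on were seen.

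The input library stood above the saline IP libraries in counts that belong to no gene and enter no comparison. Reads without a feature took 9.52% of its reads, against at most 7.14% in saline IP, and ambiguous reads took 5.65%, against at most 1.80%. Both are signals in counts outside the main measurement. With 1 input library, the spread of these shares is not known, and no cause was tested.

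The 3 libraries numbered 3 stood apart from the other 6 on the first principal component. In a fit of group and replicate number, 1541 genes differed among replicate numbers and 0 differed between replicates 1 and 2. Of the genes matched to the annotation, 1545 differed; after removal of each library's GC trend 1327 differed, 1190 of them among the 1545, and after removal of its length trend 1517, with 1204 among the 1545, which excludes either trend as the whole cause. Depth is excluded as well, since the libraries numbered 3 lay inside the range of the others (mean 44.98 M counts). Less carry-over of unbound RNA in the libraries numbered 3 would lower nuclear noncoding RNAs along with oligodendrocyte markers. In cocaine and yoked the former shifted by 0.13 (quartiles -0.18 to 0.40), against that prediction, and the latter by -1.12. Interneuron (-0.67) and astrocyte (-0.44) markers fell too, and meningeal markers, higher in IP, rose (0.50). Microglial markers, lower in IP, also rose (0.39). By library, the microglial median relative to the IP mean was 0.26, -0.02 and 0.13 in cocaine and -0.82, 0.20 and 0.45 in yoked. That rise thus lay in yoked, where replicate 1 was low. The shift had a Spearman correlation of 0.09 with the ratio of saline IP (replicates 1 and 2) to input. The 12 nuclear RNAs need not stand for all unbound RNA, so carry-over is not excluded. Saline was not tested. The labels name nothing that the libraries numbered 3 share beyond the number, so no biological explanation was tested.

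Ribosomal protein transcripts were lower in cocaine and yoked than in saline, with a median of -0.28 (quartiles -0.38 to -0.19) for the other 6 libraries against saline. Removing each library's length trend left -0.0903 (quartiles -0.20 to 0.00), and -0.09 when the trend was fitted without this list and the oxidative phosphorylation list, whose median went from -0.25 to -0.04, so a trend tied to transcript length, of unknown source, is a candidate explanation for most of the shift; removing the GC trend left -0.26, which excludes that trend. Within replicate numbers cocaine lay below saline in 3 of 3 and yoked in 2 of 3, but 13 of the 84 choices of 3 libraries had as large a median difference as the real -0.29, and so had 2 of the 27 choices of 1 library per replicate number (highest other 0.33), so chance is not excluded. No lane held IP libraries of more than 1 group (0 lanes), so lane remains open. A response of the translation machinery to cocaine or yoked treatment may also give the shift and was not tested, since these transcripts are short and the correction to -0.0903 would remove a real change in short transcripts too.

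Meningeal transcripts were far higher in IP than in input. Nonspecific binding of abundant RNA would bring oligodendrocyte transcripts, which are abundant in input. Their median was -2.02, and -2.88 to -0.93 across the 9 IP libraries, which argues against such binding for oligodendrocyte transcripts only. That list was not called with an estimated correlation (adjusted p = 0.390) or with fry (0.0926). With 1 such list and 1 input, nonspecific binding that favours other RNAs is not excluded. Excitatory neuron markers stayed near the input, with medians of -0.34 to 0.06 across the 9 IP libraries. The meningeal markers Slc13a4, Col1a2 and Dcn were at low levels in the input, so the oligodendrocyte list bears on them only indirectly. More meninges in the tissue of the IP libraries than of the input remains open, since there was 1 input library. Activity of the transgene in meningeal cells could also give the pattern, and the -2.02 of the oligodendrocyte list does not bear on it; it was not tested.

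The libraries were also regrouped for each comparison, with the real grouping counted among the splits. For cocaine against saline, yoked against saline and cocaine against yoked, the real value was 0 genes and the highest other 0, and the 10 splits of the 6 libraries are too few to give a share under 0.05. For the joint test, 100 of the 280 possible splits were drawn, the real value was 0 genes and the highest other 3936. With a real value of 0, every split gives at least as many (10 of 10 and 100 of 100), so these tallies decide nothing about chance. Of the drawn splits, 4 called a gene, and the 2 that put all libraries numbered 3 in one group had a median of 2685 genes, against 0 for the others (29 the highest). At an unadjusted p under 0.05, 78 drawn splits called more genes than the 268 of the real groups, in fits without the replicate number. The split by replicate number called 4012 genes at that threshold and 1532 at an adjusted p under 0.05.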

How the results depend on the processing

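Of the alternatives, leaving out all libraries numbered 3 and leaving out Rn45s and Lars2 were chosen only after the data were seen. The other alternatives were set before the data were examined. The counts of 0 genes in the contrasts between IP groups stayed at 0 under every alternative. Against input the count of 2089 stayed between 1464 (without saline replicate 1) and 2704 (DESeq2) except with a minimum change of 2-fold (glmTreat), which by its stricter question left 828. Genes lower in IP, 785 in the main test, ranged from 417 (without saline replicate 1) to 1172 (mean of all 9 IP libraries) at no minimum change. Over all alternatives, 1804 of 1873 values of named genes kept direction and side of the threshold, 10 passed only under the alternative, 8 no longer passed and 51 changed sign. All sign changes were in genes that did not pass a test, and their cause was not tested. Of the 612 values of called lists, 473 kept their call, 135 lost it and 4 reversed.

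With an estimated correlation, 0 lists were called for cocaine against saline, 0 for yoked against saline, 0 for cocaine against yoked and 1 against input. That test allows for members moving together within libraries. With fry, 0, 0 and 0 lists were called in the contrasts between IP groups and 19 against input. There fry did not call 8 lists that camera called: oligodendrocyte (adjusted p = 0.0926), interneuron (0.0824), layer 5 pyramidal tract (0.0735), presynaptic (0.128), glutamate receptors (0.131), microglia (0.169), oxidative phosphorylation (0.205) and voltage-gated channels (0.239). The libraries share replicate numbers, and same-number correlations of residuals ran from -0.0362 to 0.321, with 6 of 9 pairs over 0.1, but the labels state no pairing. With the replicate block, which tests the same contrasts within replicate numbers, 0 genes were called in each contrast and 12 lists for cocaine against yoked instead of 6. The correlation of the cocaine-saline and yoked-saline fold changes went from 0.589 (simulated 0.503) to 0.673 for genes with an average log2 CPM of at least 5, where unchanged groups simulated 0.494 (0.471 to 0.524) and the covariance was 0.00266 below the simulated one. As genes were simulated independently, the simulated range may be too narrow. The simulated covariance may also be too large, since differences between replicate numbers were drawn as independent noise. A covariance below it does not show that no change is shared.

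Leaving out all libraries numbered 3 turned Junb to 0.21, Gfap to 0.0420 and Cx3cr1 to -0.0749 for yoked against saline, and S100a10 to 0.0927, Fosb to 0.0817 and Bdnf to 0.0192 for cocaine against yoked. With limma-voom, Bdnf was at 0.00167 for cocaine against yoked. Against input, Junb and Slc17a7, both near 0, turned to -0.00499 and -0.00792 with RLE factors, -0.0127 and -0.0177 without a filter, -0.00398 and -0.00695 with DESeq2, and -0.0213 and -0.0216 for the mean of all 9 IP libraries. Rpl10a turned to 0.0273 with library sizes only. Fos passed with library sizes only (adjusted p = 0.0358), DESeq2 (0.0176), all 9 IP libraries (0.0162) and without saline replicate 1 (0.0369). Without a filter and with only the 4 saline libraries, Gad1 (0.0383 and 0.0237) and Gfap (0.0122 and 0.0135) passed, and Gfap also with all 9 IP libraries (0.0330). Bdnf missed with only the 4 saline libraries (0.0501) and all 9 IP libraries (0.0651), and Bdnf and Cx3cr1 missed with a 2-fold minimum (0.835 and 0.275). Leaving out all libraries numbered 3 ended 1 list call, neuropeptides for cocaine against yoked (median 0.17 to 0.08, adjusted p = 0.1475). Against input, list calls lost were bait with only the 4 saline libraries (0.0691) and without a filter (0.114), glucocorticoid response with only the 4 saline libraries (0.0522) and neuropeptides without a filter (0.0815). Their medians barely moved: 1.347 and 1.329 for bait (main 1.348), 0.3405 for glucocorticoid response (main 0.3417) and -0.55 for neuropeptides (main -0.53).

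Leaving out 1 library at a time moved the number of called lists from 13 to between 7 (without saline replicate 1) and 15 for cocaine against saline, from 9 to between 6 (without saline replicate 2) and 15 (without saline replicate 3) for yoked against saline, and from 6 to between 5 and 12 (without yoked replicate 2 or 3) for cocaine against yoked. Lists that reversed were, for yoked against saline, interferon response (-0.32 to 0.0510), interneuron (-0.47 to 0.0562) and voltage-gated channels (-0.0753 to 0.36), and, for cocaine against yoked, meningeal fibroblasts (-0.38 to 0.0908). The cause was not tested.

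Named genes that changed sign when 1 library was left out ranged as follows. For cocaine against saline: Junb -0.10 to 0.17, Malat1 -0.0323 to 0.30 and Slc17a7 -0.59 to 0.25. For yoked against saline: Junb -0.41 to 0.10, Slc17a7 -0.32 to 0.51, Gad1 -0.63 to 0.17, Gfap -0.83 to 0.76 and Cx3cr1 -0.26 to 0.50. For cocaine against yoked: S100a10 -0.16 to 0.0162, Rpl10a -0.29 to 0.00410, Fos -0.14 to 0.12, Fosb -0.23 to 0.18, Junb -0.0371 to 0.46, Egr1 -0.0433 to 0.26, Bdnf -0.20 to 0.15, Malat1 -0.59 to 0.14 and Slc17a7 -0.68 to 0.15. Against input: Rpl10a -0.20 to 0.0384, Junb -0.12 to 0.16, Arc -0.0672 to 0.52 and Slc17a7 -0.43 to 0.17.

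The common biological coefficient of variation among the IP libraries was 24.01%, and the median SE of a log2 fold change was 0.226 over all genes and 0.169 over genes with an average log2 CPM of at least 5. No other depth was tried, so how far depth limits these contrasts was not tested.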

Other observations

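The tests in this part, of how the libraries numbered 3 differ from the others, were chosen only after the principal components had been seen.

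Over the 3 groups together, the libraries numbered 3 held more RNA of voltage-gated channels, glutamate and GABA receptors and the meninges than those numbered 1 and 2, and less RNA of oligodendrocytes and interneurons. These list calls were lost with an estimated correlation (adjusted p from 0.189 to 0.371). The order did not hold within every group: the oligodendrocyte median relative to the IP mean was -0.39 in saline replicate 3 and -0.61 in saline replicate 1. In a fit of group and replicate number, 1561 genes were higher and 1040 lower in replicate 3 than in replicates 1 and 2 (edgeR, 2601 in all). The genes given here were chosen after their values were seen. Cd74, the invariant chain of antigen presentation, rose by 1.37 ± 0.11 (adjusted p = 6.05e-05), and H2-Eb1 (1.75 ± 0.19) and H2-Ab1 (1.36 ± 0.15), which encode class II chains, rose with it. The excitatory transporter gene Slc17a7 (1.0 ± 0.10), the calcium channel gene Cacna1a (1.05 ± 0.11), the GABA receptor gene Gabbr2 (1.01 ± 0.11) and the collagen gene Col1a1 (1.11 ± 0.11) also rose. The fatty acid binding protein gene Fabp7 (-1.97 ± 0.19), the carbonic anhydrase gene Car2 (-1.64 ± 0.21), the interneuron peptide gene Vip (-1.45 ± 0.21) and the transcriptional regulator Id4 (-1.28 ± 0.16) fell.

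By list, voltage-gated channels had a median of 0.56 with 33 of 52 higher, glutamate receptors 0.50 with 18 of 29 higher, GABA receptors 0.40 with 8 of 16 higher and 1 lower, and meningeal fibroblast markers 0.48 with 9 of 14 higher. Oligodendrocyte markers had a median of -0.85 with 10 of 20 lower, interneuron markers -0.82 with 11 of 24 lower, ribosomal protein genes -0.37 with 22 of 86 lower and 1 higher, and oxidative phosphorylation genes -0.36 with 33 of 82 lower. Removal of each library's length trend left -0.22 for ribosomal protein genes and -0.22 for oxidative phosphorylation genes, against -0.83 for oligodendrocyte and -0.73 for interneuron markers. Camera adjusted p for these 8 lists ranged from 2.73e-24 to 1.87e-05, and none was called with an estimated correlation, where adjusted p ranged from 0.189 to 0.498. When replicate numbers were used as groups, the joint test called 1532 genes, against 0 for the real groups.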
